A study of Rattus norvegicus with 27 samples.

How the data were processed

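Polysome-bound and total RNA of hippocampal CA1 and CA3 from male Long Evans rats were measured on Affymetrix Rat Gene 2.0 arrays. Per the labels' protocols, rats were either sham operated (non-ischemic controls, NIC) or subjected to 10 min of complete normothermic global brain ischemia, by carotid occlusion with hypotension, and 8 h of reperfusion (8R). Dissected regions of 5 rats were pooled for each replicate, a post-mitochondrial supernatant was prepared, part of it gave total RNA, and the rest was passed over a sucrose pad to pellet polysomes. The same mass of RNA was labelled for each array, so differences in the amount of RNA or in the level of translation between conditions do not appear in these values. A polysome pellet obtained over a pad is not resolved by ribosome number.

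The deposited values are intensities on a linear scale, 1 per probe set and array. PLIER and Affymetrix Expression Console are named per the submitters' processing notes, without a version. Background correction, normalization at the probe level and whether all arrays were summarised together are not given in the sources used here. The scale was read from the values, which were never below 0 and reached 9548. No centring of genes was seen. The values are single-channel intensities, so no direction had to be settled, but how arrays were scaled to each other stays unknown.

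Median intensities of the 3 arrays of a group were 31.31, 30.89 and 30.67 in NIC CA1 total RNA, 34.35, 34.51 and 32.21 in NIC CA1 polysome RNA, 32.37, 30.96 and 30.97 in NIC CA3 total RNA, and 27.25, 26.76 and 25.63 in NIC CA3 polysome RNA. After ischemia they were 30.24, 29.98, 32.08 and 31.62 in CA1 total RNA, 34.95, 33.53 and 38.09 in CA1 polysome RNA, 31.33, 31.13, 31.0 and 33.7 in CA3 total RNA, and 29.22, 27.07, 30.96 and 31.82 in CA3 polysome RNA. No arrays held identical values. Within groups the lowest correlation between arrays was from 0.946 to 0.985. The number of arrays, 3 or 4 per group, limits the precision.

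Values were taken as log2(intensity + 16), and every fold change is on that scale, which understates the change of dim transcripts. Of 36685 probe sets, 18511 carried 1 gene symbol in the platform annotation, 575 carried several and 17599 none. Of the first kind, 18394 matched a current gene record, which changed 0 symbols. Only probe sets with 1 symbol were named, and the brightest was kept for each of 18166 genes. Of these genes 291 had several probe sets. Genes with a mean below the 30th percentile (log2 of 5.39) were left out, which left 12736 genes.

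Differences were tested in R 4.3.3 with limma 3.58.1, in 1 fit of all 27 arrays with a mean for each of the 8 groups of condition, region and fraction. Moderated variances followed an intensity trend (19 residual and 10.1 prior degrees of freedom). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and genes at an adjusted p under 0.05 were called. Comparisons were 8R against NIC in each region and fraction, the difference of that change between regions, the difference between fractions (polysome change minus total change, which tests the polysome to total ratio), the difference of the latter between regions, and, among controls, CA1 against CA3 and polysome against total RNA. Adjusted p-values in the text are limma's. Counts at an unadjusted p under 0.05 stand beside low counts, where chance alone would give a share of 0.05 of the genes tested. CA1 and CA3 pools of a condition were treated as independent although they may come from the same rats.

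The groups, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where an alternative is said to have been chosen afterwards. Genes named from a comparison of 8R with NIC were the 10 with the largest rise and the 10 with the largest fall among called genes whose 8R arrays all lay above, or all below, every NIC array. In the other comparisons they were the 5 largest in each direction, and for each gene list described up to 4 members with the largest changes. Symbols that are only locus or clone names were counted and not named.

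There were 25 gene lists, covering stress responses, activity-regulated genes, the cell types that the dissected tissue can hold, synaptic genes, metabolism and the translation apparatus. A list of long noncoding RNAs had too few tested members for a test, under the minimum of 3. The others were tested with limma's camera at a preset correlation of 0.01, adjusted over 264 tests of lists and comparisons, of which 81 were called. With a correlation estimated for each list, 0 of these tests were called by camera and the lowest adjusted p was 0.0973. Camera sets a list against the other tested genes, so its direction can oppose the sign of a list's own median.

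Replicate numbers were checked for pairing by correlating the deviations of arrays from their group means. In 8R, total and polysome arrays with the same pool number in their descriptions had correlations from 0.28 to 0.77 in 7 of 7 pairs, and CA1 and CA3 arrays of the same fraction from 0.12 to 0.78 in 7 of 7 pairs. In NIC the same pairings gave -0.04 to 0.22, with 1 of 6 above 0.1, and -0.02 to 0.10, with 0 of 6 above it. The labels describe both fractions as coming from 1 supernatant, so the numbers were taken to pair the 8R fractions, whereas for NIC the values did not bear a pairing out. Polysome replicates 1, 2 and 3 of 8R CA1 were pools 1, 3 and 4. The sample codes of the NIC polysome arrays carry a suffix that the labels do not explain, so a separate preparation of these arrays, which would enter every comparison that uses them, cannot be ruled out.

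The fit was checked on simulated data over 12736 genes with known changes. For the CA1 total RNA comparison it recovered 60% of genes changed by 0.5 log2 and 95% of those changed by 1, and for CA1 polysome RNA 57% and 99%. For CA3 total RNA the shares were 59% and 98%, and for CA3 polysome RNA 61% and 99%. False calls made up 6.6%, 6.6%, 4.3% and 4.8% of the calls in these 4 comparisons. In each comparison 100 simulated genes were changed at each size. The real arrays after ischemia deviated together within pools and had a larger spread than those of controls. Whether the shares hold under such conditions was not tested, so they do not give the error rates of the real comparisons.

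Alternatives were no filter or the 50th percentile, offsets of 1 and 32, quantile normalization, median centring, a fit of only the groups compared, array quality weights, no variance trend, the mean of a gene's probe sets, a 2-fold threshold, replicate blocks and leaving out each array in turn. A fit without the 4 arrays of 8R pool 4 and a block for the 8R pools alone were added after seeing the data. Probe sets without a symbol were left out of the comparisons and counted apart.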

Results

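The study compared transcripts in total RNA with those bound to polysomes in hippocampal CA1, whose pyramidal neurons are known to die in the days after global ischemia, and in CA3, whose neurons are known to be more resistant. There were 27 arrays in 8 groups. Each NIC group had 3 arrays, 8R CA1 polysome RNA had 3, and the other 8R groups had 4, with each array a pool of 5 rats' dissected regions. The median SD of a gene within a group was from 0.0985 to 0.109 log2 in NIC and from 0.149 to 0.173 log2 in 8R. The fit used 1 variance per gene for all groups. Comparisons among NIC groups were thus tested against a spread that the 8R arrays raised. The 4 arrays of 8R pool 4 stood apart from the other 8R arrays, and their deviations from the group means correlated with each other at 0.54 to 0.78. The pool 4 arrays were kept, and counts without them are given where they moved.

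Among controls, several genes differed between CA1 and CA3 total RNA. Wfs1, an endoplasmic reticulum membrane protein used as a CA1 marker, was 3.11-fold higher in CA1 (log2 difference 1.64 ± 0.17 SE, n = 3 and 3, limma adjusted p = 3.18e-07), and the serotonin receptor genes Htr5b and Htr1b were 2.91-fold and 2.56-fold higher. Ccn3, which encodes a matricellular protein, and the potassium channel gene Kcnh7 were also higher in CA1, by 1.41 and 1.35 log2. On the other side, the zinc finger gene Plagl1 was 4.27-fold higher in CA3 (log2 difference -2.09 ± 0.17), followed by Vgll3 (-1.79), Tpd52l1 (-1.56), Vwa5al1 (-1.55) and the retinoid receptor gene Rxrg (-1.51). Of 11 tested CA1 pyramidal markers, 6 were higher in CA1, and 9 when adjusted over the list alone. The median log2 difference was 0.52 (camera adjusted p = 1.9e-12, and adjusted p = 0.159 with an estimated correlation). Of 16 CA3 pyramidal markers, 2 were lower in CA1, Kcnq5 (-0.63) and St18 (-0.62), and 2 when adjusted over the list alone (camera adjusted p = 0.0771). Oligodendrocyte and myelin markers, from a cell type outside the pyramidal layer, were higher in CA1 for 11 of 15 members, 14 when adjusted over the list alone, with Mag at 0.97, Cldn11 at 0.94 and Opalin at 0.85. The median was 0.54 (camera adjusted p = 1.12e-19, and adjusted p = 0.0973 with an estimated correlation). Immediate early genes were higher in CA1 for 7 of 26 members, 9 when adjusted over the list alone, among them Dusp6 (1.10), Nr4a1 (0.95), Arc (0.93) and Egr1 (0.87). As a list they had camera adjusted p = 1.92e-05, and adjusted p = 0.501 with an estimated correlation. In all, 306 genes were higher and 135 lower in CA1. The total of 441 fell to 286, 282 and 266 without NIC CA1 total replicate 1, 2 or 3 and to 271 and 262 without NIC CA3 total replicate 1 or 3. It was 1253 in a fit of these groups alone, 1522 with array weights and 1026 without the 8R arrays of pool 4.

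In controls, the 5 named genes most depleted from polysome RNA relative to total RNA gave a noncoding RNA, mitochondrial transcripts and transcripts of small proteins. Transcript class and length were not tested over all 1866 lower genes. Rpph1, the RNA component of ribonuclease P, was 23.6-fold lower in polysome RNA (log2 difference -4.56 ± 0.17 SE, n = 6 and 6, limma adjusted p = 1.95e-18), and the mitochondrially encoded COX2 and COX1, which cytosolic ribosomes do not translate, were 5.73-fold and 4.07-fold lower. Transcripts of the small proteins Selenow and Rpl41 were lower by 4.46-fold and 4.31-fold. Higher in polysome RNA were Pxdn, an extracellular peroxidase (3.81 ± 0.56), Ccdc25 (1.18), the ubiquitin ligase gene Herc2 (1.16), the nuclear scaffold gene Safb (1.13) and the chromatin remodeller gene Chd4 (1.13). Cytosolic ribosomal protein transcripts were lower in polysome RNA for 33 of 51 members and higher for 4, with 34 lower and 4 higher when adjusted over the list alone (median -0.34, camera adjusted p = 1.05e-13, and adjusted p = 0.378 with an estimated correlation). Synaptic and neuronal signalling genes were higher for 19 of 27 and lower for 1, the same numbers when adjusted over the list alone, among them the neurofilament genes Nefm (0.92) and Nefh (0.91) and the calcium channel genes Ryr2 (0.90) and Itpr1 (0.87). For that list camera adjusted p = 0.00226 was found, and adjusted p = 0.692 with an estimated correlation. Heat shock genes were higher for 14 of 19 and lower for 1 before any ischemia, likewise when adjusted over the list alone, with Hspd1 at 1.09 and Hsph1 at 0.90 (camera adjusted p = 0.00537, and adjusted p = 0.692 with an estimated correlation). Messenger RNA-binding and stress granule protein genes were higher for 15 of 20 and lower for 2, with no change when adjusted over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.627 with an estimated correlation). Averaged over CA1 and CA3, 4876 genes were higher and 1866 lower in polysome RNA. The 6 arrays of a fraction were 3 of each region, which may come from the same rats, and the fit did not pair the fractions.

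Among the genes named for CA1 total RNA, the largest rise after ischemia was that of Hspb1. This small heat shock protein gene rose from a mean intensity of 16.8 ± 0.98 (SD, n = 3) in NIC to 525 ± 160 (SD, n = 4) in 8R. Its log2 change was 4.00 ± 0.31 SE (limma adjusted p = 2.04e-10). Heme oxygenase Hmox1, which degrades heme, rose 4.59-fold, from 15.3 ± 1.5 to 128 ± 14. The metallothionein Mt1 rose 5.25-fold, the mitochondrial chaperone gene Hspd1 4.54-fold, and the growth arrest genes Gadd45g and Gadd45b 6.29-fold and 4.50-fold. Atf3, a stress-induced transcription factor, rose 5.42-fold, Ptgs2, the inducible cyclooxygenase, 5.25-fold, Rgs2, a regulator of G protein signalling, 5.15-fold, and Npas4, an activity-dependent transcription factor, 4.68-fold. Falls were smaller. The orphan nuclear receptor genes Nr4a3 and Nr4a1 fell by 1.25 and 0.92 log2 (adjusted p = 2.54e-11 and 2.28e-06), Nr4a3 from an intensity of 362 ± 4.5 to 144 ± 9.5. The histone gene H4c14 fell by 1.35, Entrep3 by 1.20, the calmodulin-binding factor gene Camta2 by 1.17, Fbxl16 by 1.09, Prrt2, a presynaptic protein gene, by 1.07, Htr5b by 0.99, Ubald1 by 0.95 and Trappc14 by 0.94 log2. All these genes passed limma's test, and every 8R array lay outside the range of the NIC arrays.

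The heat shock and cytosolic chaperone list held 24 symbols. Of these, Hspa1a, Hspa1b, Hspa1l, Hsp90aa1 and Ahsa1 had no probe set of their own and were not tested. Among the gene lists in CA1 total RNA, all 19 tested heat shock and cytosolic chaperone genes rose, and 19 when adjusted over the list alone. Their median log2 change was 1.03, with Hsph1 at 2.10 and Cryab at 1.97 (camera adjusted p = 1.38e-19, and adjusted p = 0.148 with an estimated correlation). Unfolded protein and integrated stress response genes rose for 18 of 27, 21 when adjusted over the list alone. They were led by the transcription factor gene Ddit3 (1.83), the phosphatase subunit gene Ppp1r15a (1.65), Chac1 (1.47) and Herpud1 (1.45), with camera adjusted p = 6.32e-09 and adjusted p = 0.272 with an estimated correlation. Late activity-induced neuronal genes rose for 10 of 16, and 10 when adjusted over the list alone (median 0.44, camera adjusted p = 4.32e-06, and adjusted p = 0.403 with an estimated correlation). The translation apparatus moved too. Cytosolic ribosomal protein genes rose for 40 of 51 and fell for 0 in limma's test, 41 and 0 when adjusted over the list alone. Rpl24 rose by 1.02, Rpl5 by 0.93 and Rps19 by 0.92 (list median 0.54, camera adjusted p = 1.73e-12, and adjusted p = 0.403 with an estimated correlation). Initiation and elongation factor genes rose for 14 of 23, 17 when adjusted over the list alone. Among them were the eIF2 subunit genes Eif2s2 (1.05) and Eif2s1 (0.84), and the list had camera adjusted p = 1.39e-06, and adjusted p = 0.298 with an estimated correlation. Oxidative stress and metallothionein genes rose for 9 of 18 and fell for 1, 10 and 1 when adjusted over the list alone, with Srxn1 at 1.40 and Mt2A at 1.02 (camera adjusted p = 0.00079, and adjusted p = 0.28 with an estimated correlation). Synaptic and neuronal signalling genes fell for 7 of 27 and rose for 1, 8 and 1 when adjusted over the list alone. The scaffold gene Shank1 was at -0.83, Syn1 at -0.65 and Rbfox3 at -0.52 (median -0.18, camera adjusted p = 0.00313, and adjusted p = 0.692 with an estimated correlation). Relative to the other 8R pools, the pool 4 array was at 0.25 for heat shock, 0.33 for late activity-induced, 0.21 for unfolded protein and integrated stress response and -0.25 for ribosomal protein genes (list medians).

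Reactive astrocyte genes rose for 8 of 17, and 8 when adjusted over the list alone. They included the filament genes Vim (1.27) and Gfap (0.96) and the protease inhibitor gene Timp1 (1.66), with camera adjusted p = 0.00809 and adjusted p = 0.627 with an estimated correlation. Microglial markers rose for 4 of 14, 5 when adjusted over the list alone, among them the complement genes C1qb (0.63) and C1qc (0.52), with camera adjusted p = 0.134. Among apoptosis and p53 target genes 7 of 18 rose and 1 fell, likewise when adjusted over the list alone. Those that rose most were Gadd45a (1.62), Mdm2 (1.17) and Cdkn1a (1.10), which are known for growth arrest and p53 feedback. The list was not called (camera adjusted p = 0.0647), and growth arrest genes were not tested apart from cell death genes. Immediate early genes went both ways, 7 of 26 up and 5 down, or 8 and 6 when adjusted over the list alone, with a median of -0.08, a mean of 0.18 and camera adjusted p = 0.593. Of glycolysis and hypoxia genes 7 of 15 rose and 1 fell, likewise when adjusted over the list alone. P4ha1 was at 1.54, Vegfa at 0.93 and the lactate dehydrogenase gene Ldha at -0.56 (camera adjusted p = 0.0731). Nuclear-encoded respiratory chain genes rose for 19 of 72 and fell for 1, 20 and 3 when adjusted over the list alone (camera adjusted p = 0.0681). The pool 4 array was at -0.28 for this list, and without pool 4 of 8R, a fit chosen after seeing the data, 44 rose and 2 fell. Cholesterol synthesis genes rose for 4 of 15 and fell for 1, and messenger RNA-binding and stress granule genes rose for 7 of 20, the same numbers when adjusted over the list alone (camera adjusted p = 0.567 and 0.0833). Camera called none of the remaining lists in this comparison. Astrocyte markers had 4 of 14 higher and 1 lower, 7 and 1 when adjusted over the list alone (camera adjusted p = 0.338). Oligodendrocyte markers had 2 of 15 higher and 2 lower, 2 and 5 when adjusted over the list alone (camera adjusted p = 0.0544). CA1 pyramidal markers had 1 of 11 higher and 2 lower, 1 and 3 when adjusted over the list alone, and CA3 pyramidal markers 2 of 16 in each direction, likewise when adjusted over the list alone (camera adjusted p = 0.0831 and 0.202). Dentate granule cell markers had 3 of 10 higher and 1 lower, 3 and 2 when adjusted over the list alone, and interneuron markers 1 of 13 higher, none when adjusted over the list alone (camera adjusted p = 0.804 for both). Inflammatory genes had 1 of 13 higher, none when adjusted over the list alone, and a median of 0.16, opposite in sign to the test (camera adjusted p = 0.942). No endothelial or choroid plexus, meningeal and blood marker was called by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.633 and 0.331).

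Across all genes in CA1 total RNA, 2563 rose and 783 fell, of which 125 and 7 changed at least 2-fold. The 8R and NIC arrays did not overlap for 34.6% of tested genes, where chance gives 5.71%. After quantile normalization 2038 rose and 1726 fell, so the share of calls that were higher was 54.1% instead of 76.6%. Without NIC CA1 total replicate 2 the total of 3346 was 2217.

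In CA3 total RNA the genes with the largest rises included several of those named for CA1. Hspb1 rose from an intensity of 9.34 ± 1.8 (SD, n = 3) to 422 ± 190 (SD, n = 4), a log2 change of 4.00 ± 0.31 SE (limma adjusted p = 7.34e-10). Atf3 rose 6.20-fold, Hmox1 4.15-fold, Zfand2a, which binds the proteasome under stress, 3.93-fold, the small heat shock gene Cryab 3.83-fold, Mt1 3.48-fold, Ddit3 3.18-fold, Gadd45g 3.10-fold, Gadd45b 3.08-fold and Ptgs2 2.92-fold. The circadian clock genes Nr1d1 and Dbp fell by 0.74 and 0.73 log2 (adjusted p = 0.00141 and 1.1e-05). Others that fell were Tlx2 (by 1.36), the actin-binding thymosin gene Tmsb4x (by 0.94), Tmem258l5 (by 0.89), H4c14 (by 0.82), Zfp580 (by 0.75), Ffar3 (by 0.73), Entrep3 (by 0.72) and Igh-6l1 (by 0.72).

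Heat shock genes rose in CA3 total RNA for 18 of 19, 19 when adjusted over the list alone (median 0.70, camera adjusted p = 1.38e-19, and adjusted p = 0.148 with an estimated correlation). Unfolded protein and integrated stress response genes rose for 20 of 27, 21 when adjusted over the list alone (median 0.50, camera adjusted p = 2.16e-09, and adjusted p = 0.252 with an estimated correlation). Ribosomal protein genes rose for 26 of 51, with 29 higher and 1 lower when adjusted over the list alone. The largest rises were in Rpl18 (0.72), Rpl9 (0.65), Rpl5 (0.63) and Rpl14 (0.59), with camera adjusted p = 3.55e-06 and adjusted p = 0.631 with an estimated correlation. Initiation and elongation factors rose for 14 of 23, 17 when adjusted over the list alone (camera adjusted p = 6.74e-06, and adjusted p = 0.334 with an estimated correlation). Late activity-induced genes rose for 9 of 16, and 9 when adjusted over the list alone (camera adjusted p = 0.00382, and adjusted p = 0.643 with an estimated correlation). Oxidative stress genes rose for 8 of 18, and 8 when adjusted over the list alone, with Srxn1 at 1.38 (camera adjusted p = 8.98e-05, and adjusted p = 0.218 with an estimated correlation). Of apoptosis and p53 target genes 7 of 18 rose, and 7 when adjusted over the list alone, again with Cdkn1a (1.25), Gadd45a (0.94) and Mdm2 (0.70) first (camera adjusted p = 0.03, and adjusted p = 0.394 with an estimated correlation). Glycolysis and hypoxia genes rose for 4 of 15, 6 when adjusted over the list alone (camera adjusted p = 0.0317, and adjusted p = 0.378 with an estimated correlation). Reactive astrocyte genes rose for 6 of 17, with 7 higher and 1 lower when adjusted over the list alone, including Vim (1.38) and Gfap (1.04), with camera adjusted p = 0.113. Synaptic genes had a median of 0.13, which was -0.01 after quantile normalization, with 3 of 27 higher and 1 lower, likewise when adjusted over the list alone (camera adjusted p = 0.773). Among oligodendrocyte markers 4 of 15 rose, and 4 when adjusted over the list alone, with Mobp at 0.74 and Mbp at 0.41 (camera adjusted p = 0.303). The pool 4 array was at 0.18 for heat shock, 0.29 for late activity-induced, 0.25 for reactive astrocyte, 0.17 for unfolded protein and integrated stress response, -0.20 for initiation and elongation factor and -0.23 for ribosomal protein genes relative to the other 8R pools.

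Across all genes in CA3 total RNA, 1806 rose and 170 fell, of which 37 and 1 changed at least 2-fold, and the 8R and NIC arrays did not overlap for 24.6% of genes against 5.71% by chance. Quantile normalization gave 1064 and 541, or 66.3% higher instead of 91.4%. The total of 1976 was 976 without NIC CA3 total replicate 2, 1257 without 8R CA3 total replicate 1, 3013 without 8R CA3 total replicate 4 and 4748 with array weights. It was 4355 (3709 higher and 646 lower) without the 4 arrays of 8R pool 4, a fit chosen after seeing the data.

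**Figure D1:**
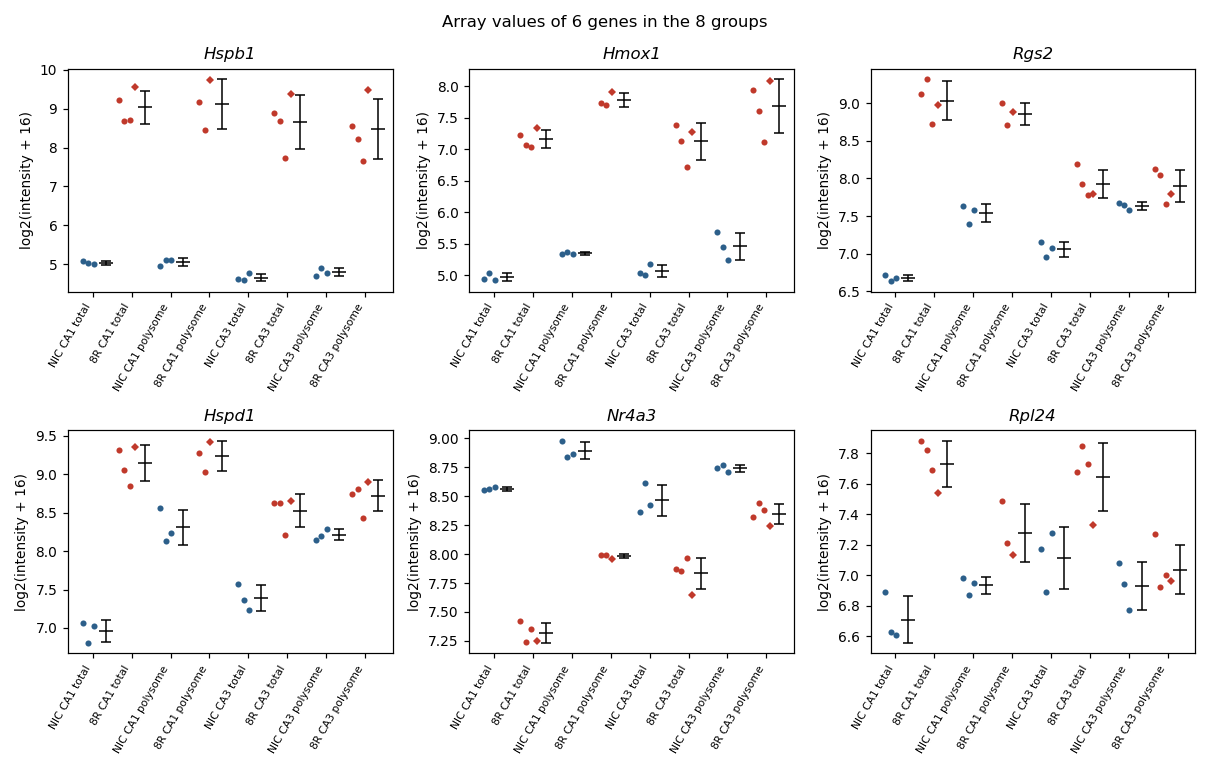
Each point is 1 array of 1 of the 8 groups (NIC in blue, 8R in red, with pool 4 of 8R as diamonds), the vertical axis is log2(intensity + 16), and black bars show the group mean ± SD. Hspb1 and Hmox1 rose in both regions and fractions, Nr4a3 was lower in 8R than in NIC in each region and fraction, and Rgs2, Hspd1 and Rpl24 rose more in CA1 total than in CA1 polysome RNA, by 1.04, 1.25 and 0.68 log2.

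The regions were compared directly by testing the difference of their changes. Rgs2 rose more in CA1 than in CA3 in total RNA, by 1.5 ± 0.18 log2 (limma adjusted p = 3.16e-05), with a change of 2.36 in CA1 and 0.86 in CA3, and in polysome RNA by 1.05 ± 0.18 (adjusted p = 0.0297). In total RNA, Hspd1 rose more in CA1 by 1.04 ± 0.20 (adjusted p = 0.0425) and Pnrc2, a nuclear receptor coactivator gene, by 0.84 ± 0.15 (adjusted p = 0.0382). The call of Hspd1 rested on 1 of its probe sets, since the other was at 0.60, and with their mean Hspd1 no longer passed, at 0.82 and adjusted p = 0.346. In polysome RNA, Polm, a DNA polymerase gene, differed by -1.05 ± 0.19 (adjusted p = 0.0297), with a change of -0.15 in CA1, which did not pass, and 0.90 in CA3. These were the 3 genes called in total RNA and the 2 called in polysome RNA, with 664 and 707 at an unadjusted p under 0.05. Both numbers were near a share of 0.05 of the 12736 genes tested, which chance alone would give. Late activity-induced genes had a larger change in CA1 total RNA as a list, by a median of 0.33 (1 of 16 called, 4 when adjusted over the list alone, camera adjusted p = 2.99e-08, and adjusted p = 0.291 with an estimated correlation). Ribosomal protein genes were at 0.21 and heat shock genes at 0.17 (camera adjusted p = 2.77e-10 and 1.37e-08, and adjusted p = 0.501 and 0.334 with an estimated correlation), with 0 of 51 and 1 of 19 called by limma, and 0 and 3 when adjusted over the list alone. For oligodendrocyte markers, CA3 pyramidal markers and synaptic genes the log2 change after ischemia was lower in CA1 than in CA3 total RNA. The median differences were -0.32, -0.22 and -0.25 (camera adjusted p = 6.9e-08, 0.000332 and 7.99e-07, and adjusted p = 0.291, 0.291 and 0.625 with an estimated correlation). No member of these 3 lists was called by limma, over all genes or adjusted over the list alone.

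The log2 changes of the regions correlated across genes in total RNA (Pearson r = 0.83) and in polysome RNA (r = 0.66), although genes are not independent replicates. Same-numbered CA1 and CA3 arrays of 8R deviated together in 7 of 7 pairs (correlations of 0.12 to 0.78), which adds to any overlap, so the numbers for independent lists below are no test. In total RNA 1474 genes rose in both regions, where independent lists would share 363, and 123 fell in both, where they would share 10.5. In polysome RNA the numbers were 154 against 14.7 and 19 against 1.21. The called counts between regions rested on single arrays. In total RNA the 3 became 1 without NIC CA1 total replicate 2 or 3, NIC CA3 total replicate 1 or 3, 8R CA1 total replicate 1, 2 or 4, or 8R CA3 total replicate 2 or 3. It became 7 without 8R CA3 total replicate 4. In polysome RNA the 2 became 0 in limma without any of the 6 NIC polysome arrays, 8R CA1 polysome replicate 1 or 8R CA3 polysome replicate 3 or 4, with 498 to 1025 genes at an unadjusted p under 0.05, 1 without 8R CA3 polysome replicate 2, and 3 without 8R CA1 polysome replicate 2 or 3. With the pool number as a replicate block the counts were 16 and 4, without the 8R arrays of pool 4 they were 15 and 1, with array weights 22 and 4, and after quantile normalization 1 gene was higher and 1 lower in total RNA.

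Among the genes named for CA1 polysome RNA, the largest rise was again that of Hspb1, and the falls were smaller. Hspb1 rose 16.7-fold, from an intensity of 17.4 ± 2.1 (SD, n = 3) to 578 ± 250 (SD, n = 3), with a log2 change of 4.06 ± 0.33 SE and limma adjusted p = 2.62e-09. Mt1 rose 7.10-fold, Npas4 5.91-fold, Hmox1 5.42-fold, Ptgs2 4.98-fold, the co-chaperone gene Bag3 4.72-fold, Cryab 4.67-fold, Zfand2a 4.29-fold, Gadd45g 4.11-fold and Lox, a collagen cross-linking enzyme, 3.76-fold. Lox was dim in NIC and variable in 8R, at 10.6 ± 5.9 (SD, n = 3) and 110 ± 100 (SD, n = 3), with limma adjusted p = 0.00248. Kctd4 fell by 1.20 log2 (adjusted p = 0.000738), and Nr4a2 and Nr4a3 by 0.92 and 0.91 (adjusted p = 1.88e-05 and 1.99e-07). Htr5b fell by 0.93, the calcium-dependent kinase genes Camk4 and Camkk2 by 0.91 and 0.86, Neurod6, a transcription factor of pyramidal neurons, by 0.90, Diras2 by 0.86 and the growth cone protein gene Gap43 by 0.85. Gstm6, a glutathione transferase gene, fell by 0.92.

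Heat shock genes rose in CA1 polysome RNA for 11 of 19, 12 when adjusted over the list alone (median 0.55, camera adjusted p = 1.33e-16, and adjusted p = 0.175 with an estimated correlation). Late activity-induced genes rose for 7 of 16, 10 when adjusted over the list alone, with the activin subunit gene Inhba at 1.39 (camera adjusted p = 8.72e-11, and adjusted p = 0.233 with an estimated correlation). Unfolded protein and integrated stress response genes rose for 9 of 27, 14 when adjusted over the list alone, with Ddit3 at 1.72 and Ppp1r15a at 1.67 (camera adjusted p = 9.49e-07, and adjusted p = 0.334 with an estimated correlation). Synaptic genes fell for 6 of 27, 14 when adjusted over the list alone. Nefm was at -0.59, Nefl at -0.55 and the sodium channel gene Scn2a at -0.55 (median -0.29, camera adjusted p = 2.27e-06, and adjusted p = 0.627 with an estimated correlation). Of 11 CA1 pyramidal markers 1 fell, Meis2 (-0.65), and 3 when adjusted over the list alone (median -0.33, camera adjusted p = 0.00639, and adjusted p = 0.627 with an estimated correlation). Reactive astrocyte genes rose for 6 of 17, 7 when adjusted over the list alone, with Timp1 at 1.85 and Vim at 1.41 (camera adjusted p = 2.46e-06, and adjusted p = 0.291 with an estimated correlation). Microglial markers rose for 4 of 14, 5 when adjusted over the list alone, where C1qb was at 1.00 and C1qc at 0.79 (camera adjusted p = 0.000174, and adjusted p = 0.334 with an estimated correlation). Ribosomal protein genes had a median of 0.24, with 4 of 51 higher, 10 when adjusted over the list alone (camera adjusted p = 1.57e-06, and adjusted p = 0.627 with an estimated correlation). Oxidative stress genes rose for 5 of 18 and fell for 1, 6 and 1 when adjusted over the list alone, with Mt2A at 1.63 (camera adjusted p = 0.00079, and adjusted p = 0.28 with an estimated correlation). Here the pool 4 array was at 0.27 for heat shock, 0.29 for late activity-induced, 0.25 for unfolded protein and integrated stress response, 0.33 for reactive astrocyte, 0.23 for microglial, -0.22 for CA1 pyramidal and -0.24 for ribosomal protein genes relative to the other 8R pools.

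Across all genes in CA1 polysome RNA, 619 rose and 439 fell, of which 60 and 1 changed at least 2-fold, and 24.2% of genes did not overlap against 10% by chance. Quantile normalization gave 646 and 658 and median centring 395 and 414, so 49.5% and 48.8% of calls were higher instead of 58.5%. The total of 1058 moved with each array left out, to 600, 572 and 632 without NIC CA1 polysome replicate 1, 2 or 3 and to 540, 1788 and 423 without 8R CA1 polysome replicate 1, 2 or 3. It was 447 in a fit of these groups alone and 2194 with array weights.

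In CA3 polysome RNA fewer genes were called. Hspb1 rose 12.8-fold, from an intensity of 11.8 ± 1.9 (SD, n = 3) to 381 ± 220 (SD, n = 4), with a log2 change of 3.68 ± 0.31 SE and limma adjusted p = 5.67e-09. Hmox1 rose 4.69-fold, Cryab 4.34-fold, Atf3 3.98-fold, Zfand2a 3.83-fold, Mt1 3.75-fold, Mt2A 2.97-fold, Vim 2.72-fold, Mt1f 2.62-fold and Bag3 2.57-fold. Nr4a2 fell by 0.87 and Dbp by 0.75 log2 (adjusted p = 4.03e-05 and 2.59e-05). Or13c3c fell by 0.93, Cyp11b3 by 0.86, the poly(A)-binding protein gene Pabpc4l by 0.77, Fsd1 by 0.61, Wdr17 by 0.58 (its other probe set was at -0.05, and with the mean of its probe sets it no longer passed), the splicing factor gene Luc7l3 by 0.58, Vgll3 by 0.57 and the potassium channel subunit gene Kcnv1 by 0.56.

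Heat shock genes rose in CA3 polysome RNA for 10 of 19, 12 when adjusted over the list alone (median 0.40, camera adjusted p = 5.21e-15, and adjusted p = 0.215 with an estimated correlation). Reactive astrocyte genes rose for 6 of 17, 9 when adjusted over the list alone, with S100a10 at 0.83 (camera adjusted p = 5.07e-08, and adjusted p = 0.233 with an estimated correlation). Unfolded protein and integrated stress response genes rose for 6 of 27, 11 when adjusted over the list alone, and late activity-induced genes for 5 of 16, 10 when adjusted over the list alone (camera adjusted p = 1.92e-05 and 4.38e-05, and adjusted p = 0.412 and 0.501 with an estimated correlation). Among initiation and elongation factors 3 of 23 rose, with 6 higher and 1 lower when adjusted over the list alone. Eif4ebp1, a repressor of cap-dependent translation, was at 0.57 (camera adjusted p = 0.0141, and adjusted p = 0.66 with an estimated correlation). Ribosomal protein genes had a median of 0.10, which was -0.01 after median centring, with 3 of 51 higher, 4 when adjusted over the list alone (camera adjusted p = 0.326). Microglial markers rose for 2 of 14, 4 when adjusted over the list alone, with C1qb at 0.96 (camera adjusted p = 0.00501, and adjusted p = 0.51 with an estimated correlation). No synaptic gene of 27 was called by limma, over all genes or adjusted over the list alone (median -0.06, camera adjusted p = 0.0557). The pool 4 array was at 0.26 for heat shock, 0.31 for late activity-induced, 0.31 for reactive astrocyte, 0.09 for unfolded protein and integrated stress response, 0.30 for microglial and -0.12 for ribosomal protein genes relative to the other 8R pools.

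Across all genes in CA3 polysome RNA, 303 rose and 35 fell, of which 21 and 0 changed at least 2-fold in limma's fit, with 2386 at an unadjusted p under 0.05, and 17.7% of genes did not overlap against 5.71% by chance. Median centring moved the median of all genes from 0.039 to -0.065 and gave 76 higher and 44 lower, quantile normalization gave 125 and 47, and the share higher was thus 63.3% and 72.7% instead of 89.6%. The total of 338 was 153, 112 and 89 without NIC CA3 polysome replicate 1, 2 or 3, 112 without 8R CA3 polysome replicate 4, 147 in a fit of these groups alone, 202 with the 50th percentile filter and 744 with array weights.

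**Figure D2:**
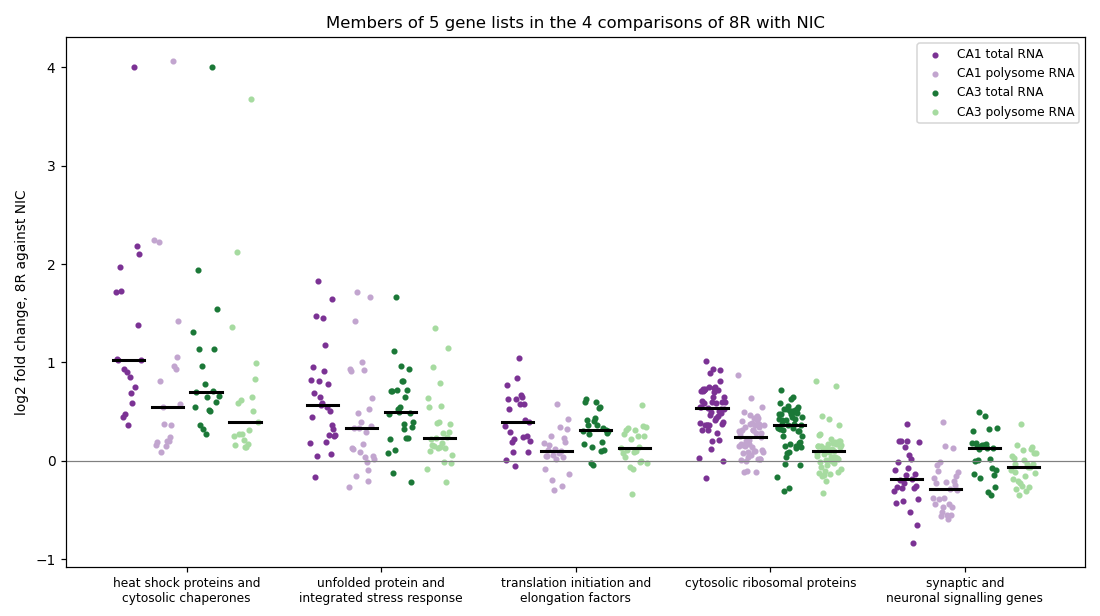
Each dot is 1 member of 1 of 5 gene lists, placed at its log2 change of 8R against NIC (vertical axis) in 1 of the 4 comparisons of region and fraction, and black lines are medians. Heat shock medians were 1.03, 0.55, 0.70 and 0.40 in CA1 total, CA1 polysome, CA3 total and CA3 polysome RNA, and ribosomal protein medians 0.54, 0.24, 0.37 and 0.10, the last being -0.01 after median centring.

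Whether a transcript's polysome to total ratio changed was tested as the difference between the changes in the fractions. In CA1, several transcripts that rose in total RNA rose less in polysome RNA. Hspd1 rose by 2.18 log2 in total and 0.93 in polysome RNA, a difference of -1.25 ± 0.20 SE (limma adjusted p = 0.0039). Its other probe set was at -0.80. Rgs2 rose by 2.36 and 1.32, a difference of -1.04 ± 0.18 (adjusted p = 0.00668). Larger negative differences than that of Rgs2 were found for Ociad2 (-1.15), Ccdc25 (-1.12), the isoprenoid synthesis gene Idi1 (-1.11) and the transcription factor gene Cebpg (-1.08). Positive differences were found for Rpph1 (1.64 ± 0.33), H4c14 (1.38), Ffar3 (0.97), the AMPA receptor auxiliary subunit gene Cnih2 (0.94) and Lgals5 (0.86). Rpph1 is a noncoding RNA that was at -4.56 in polysome against total RNA of controls, so its ratio does not report translation. Whether RNA not bound to polysomes entered the pellets was not tested. In CA3, Scg5, a chaperone of the secretory pathway, was at -1.05 ± 0.17 (adjusted p = 0.00873), with Lrpap1 at -0.96, the disulfide isomerase gene Pdia6 at -0.93, Crtac1 at -0.87 and the splicing factor gene Srsf2 at -0.85. Positive differences in CA3 were those of Polm (1.08 ± 0.18), Pate6l (1.01), Ahrr (0.99), Rpl23al1 (0.94) and Fancd2osl1 (0.91).

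By list, heat shock genes had a lower polysome to total ratio after ischemia in CA1 for 6 of 19, 10 when adjusted over the list alone. Dnaja1 was at -0.92 and Cacybp at -0.88 (list median -0.38, camera adjusted p = 9.85e-05, and adjusted p = 0.625 with an estimated correlation). Initiation and elongation factors were lower for 4 of 23, 10 when adjusted over the list alone, with Eif2s1 at -0.83 (camera adjusted p = 0.000414, and adjusted p = 0.501 with an estimated correlation). Ribosomal protein genes were lower for 2 of 51, 5 when adjusted over the list alone, with Rpl24 at -0.68 (median -0.34, camera adjusted p = 0.000319, and adjusted p = 0.692 with an estimated correlation). Of the unfolded protein and integrated stress response list 4 of 27 members were lower in CA1, Calr (-0.82), Pdia3 (-0.79), Hsp90b1 (-0.74) and Pdia6 (-0.71), 5 when adjusted over the list alone (camera adjusted p = 0.0515). Other chaperones of that list did not pass, with Hspa5 at -0.27 and Hyou1 at -0.14. In CA3 that list had 2 lower members, Pdia6 (-0.93) and Hsp90b1 (-0.67), 5 when adjusted over the list alone (camera adjusted p = 0.0482, and adjusted p = 0.692 with an estimated correlation). Heat shock and ribosomal protein genes had medians of -0.30 and -0.28 in CA3 (camera adjusted p = 0.00748 and 0.00279, and adjusted p = 0.692 and 0.719 with an estimated correlation), with 0 members called by limma over all genes. Adjusted over the list alone, 5 heat shock genes were lower in CA3, and 5 ribosomal protein genes were lower and 2 higher.

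The ratio changed for 52 genes upwards and 434 downwards in CA1 and for 7 and 14 in CA3. It differed between the regions for 0 genes in limma's test, with 249 at an unadjusted p under 0.05. That number was below a share of 0.05 of the 12736 genes tested, which chance alone would give. With the pool as a replicate block the counts were 2642 (548 and 2094) in CA1 and 2179 (744 and 1435) in CA3, and with a fixed block 3129 and 2824. A block in the 8R pools only, added after seeing the data, gave 1614 and 721. With array weights they were 1544 and 2207, and without pool 4 of 8R 1081 and 1254. Quantile normalization gave 165 and 317 in CA1, 34.2% higher instead of 10.7%, and 10 and 8 in CA3, 55.6% instead of 33.3%, which median centring moved to 20.0%. In CA1 the total of 486 was 151, 315 and 205 without NIC CA1 polysome replicate 1, 2 or 3, 31 without NIC CA1 total replicate 2, 975 and 100 without 8R CA1 polysome replicate 2 or 3, and 150 without 8R CA1 total replicate 1. In CA3 the total of 21 was 8 and 3 without NIC CA3 polysome replicate 2 or 3, 8 and 13 without NIC CA3 total replicate 2 or 3, 35, 164, 10 and 13 without 8R CA3 polysome replicate 1, 2, 3 or 4, and 12 and 1023 without 8R CA3 total replicate 1 or 4. The correlation across genes of the polysome with the total change was 0.49 in CA1 and 0.23 in CA3. In CA1, 471 genes rose in both fractions where independent lists would share 125, and 6 changed in opposite directions. Fractions of an 8R pool deviated together in 7 of 7 pairs (0.28 to 0.77), so this overlap is no test either.

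Considering the 4 comparisons of 8R with NIC together, 111 genes rose in all of them and 6 fell in all of them. The 6 that fell, singled out after their values were seen, were Dbp, the nuclear receptor genes Nr4a2, Nr4a3 and Nr3c2, the sphingosine phosphate receptor gene S1pr1 and Ctc1, a telomere maintenance gene.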

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

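Among the tests in this part, the one for a weaker response in pool 4 was chosen after the result was seen, as were the fits without pool 4, the slope measure of polysome enrichment and the test of its polysome part.

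The 4 arrays of 8R pool 4, 1 in each region and fraction, deviated together from the other 8R arrays (correlations of 0.54 to 0.78), and array weights gave them 0.28 and 0.46 in CA1 polysome and total RNA and 0.26 and 0.28 in CA3. The activity-dependent gene Npas4 was higher in them by 1.19, 1.00, 1.12 and 1.24 log2 in CA1 polysome, CA1 total, CA3 polysome and CA3 total RNA, and Itpka was at -1.33, -0.77, -1.12 and -0.89, both singled out after their values were seen, while the list with the largest difference below 0 in CA1 polysome RNA, respiratory chain genes, was at -0.46, -0.28, -0.33 and -0.24. The tables argue against a different make-up of cell types by 0.2 log2 or more in every group, since no cell-type list with 1 sign in all 4 groups exceeded 0.11 in the group where it was smallest (microglial markers 0.23, 0.14, 0.30 and 0.11, CA1 pyramidal markers -0.22, -0.11, -0.16 and -0.21), and against a level or scale difference, since the lowest correlation was 0.53 after quantile normalization. A weaker response to ischemia in these rats as a whole stays open. The 154 genes that rose in all 4 comparisons without pool 4 lay below the other pools in 1 of 4 groups, but with medians near 0 (0.07, 0.10, 0.02 and -0.05). By list the sign differed. Heat shock genes were at 0.27, 0.25, 0.26 and 0.18 and late activity-induced genes at 0.29, 0.33, 0.31 and 0.29, so the medians of these lists were not weaker in pool 4. Ribosomal protein genes were at -0.24, -0.25, -0.12 and -0.23, and oxidative stress and metallothionein genes at -0.16, -0.05, -0.20 and -0.17. A difference in cell make-up that is smaller, or larger in only some of the groups, stays open, with choroid plexus, meningeal and blood markers at 0.29, -0.09, 0.40 and 0.38. A difference in the animals, the surgery or the handling of that pool stays open as well, and was not tested.

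The change in the polysome to total ratio passed the test for 486 genes in CA1 and 21 in CA3, in a fit that ignores the pairing of the 8R fractions. With the pool as a replicate block 2642 and 2179 genes passed, so the first counts do not show a larger change in CA1. The change went against the enrichment seen in controls. The slope of a pool's polysome minus total difference on that of the controls of the other region was 0.87 ± 0.04 (SD, n = 3) in NIC CA1 and 0.48 ± 0.10 (n = 3) in 8R CA1, and 0.94 ± 0.02 (n = 3) and 0.52 ± 0.12 (n = 4) in CA3. The tables argue against NIC polysome arrays alone being out of place as the whole cause, since the total RNA change itself followed the control difference (r = 0.24 in CA1 and 0.43 in CA3), against a level or scale difference, since the smaller drop was -0.34 after quantile normalization, and against pool 4 alone, since it was -0.34 without that pool. For the polysome part (r = -0.27 in CA1 and -0.26 in CA3), NIC polysome arrays prepared apart cannot be told apart from ischemia. The unexplained suffix of their codes leaves such a preparation open. A batch that separates all NIC from all 8R arrays cannot be told apart from ischemia either. RNA in the pellets that is not bound to polysomes was not measured. A smaller polysome enrichment after ischemia is therefore a hypothesis.

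Differences between the regions passed the test for 3 genes in total RNA, Rgs2 (1.5), Hspd1 (1.04) and Pnrc2 (0.84), and for 2 in polysome RNA, Rgs2 (1.05) and Polm (-1.05).

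Single arrays far from the other 3 of their group, by the gap to the nearest as a share of the range, were found for 10 of 132 values checked, where chance gives about 1 in 20, and 5 of the 10 were in pool 4. In 8R CA1 total RNA these were the mean of inflammatory genes in replicate 2 (share 0.85, at 5.97 against 6.03), CA1 pyramidal markers in replicate 3 (0.836, 7.22 against 6.79), dentate granule cell markers in replicate 2 (0.83, 6.65 against 7.04), and in replicate 3 Camta2 (0.905, 8.97 against 8.4) and Fbxl16 (0.874, 9.45 against 8.93). In replicate 4 of 8R CA3 total RNA they were translation factors (0.858, 8.13 against 8.32), respiratory chain genes (0.954, 8.22 against 8.44) and Mt1 (0.857, 10.82 against 9.5). In replicate 4 of 8R CA3 polysome RNA they were respiratory chain genes (0.978, 7.79 against 8.12) and Kcnv1 (0.914, 5.45 against 5.66).

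Probe sets without a gene symbol, which the comparisons left out, were called in numbers of 898 (681 higher and 217 lower) of 6900 in CA1 total, 156 (123 and 33) in CA1 polysome, 360 (306 and 54) in CA3 total and 186 (172 and 14) in CA3 polysome RNA.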

How the results depend on the processing

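The settings without the 8R pool 4 arrays and with a block in the 8R pools only were chosen after the results were seen. Of 2794 values for named genes and lists under the alternatives, 2505 stayed on their side of the threshold, 268 were weaker and 21 were stronger. Some medians of lists near 0 did change sign with the scaling or without pool 4, such as synaptic genes in CA3 total RNA (0.13, and -0.01 after quantile normalization). With each array left out, 908 of 1058 stayed and 150 were weaker. Counts were less stable, and where a value below does not show it the cause was not tested. Dim signal limits the precision, since from 27.4% to 36.8% of an array's probe sets lay below an intensity of 16. With no filter the counts were 4 for the region difference in polysome RNA and 34 for the fraction difference in CA3, and with the 50th percentile filter 202 in CA3 polysome RNA. With an offset of 1 the fraction difference in CA3 had 32. CA3 polysome RNA had 172 after quantile normalization and 120 after median centring. With only the groups compared, which changes both the arrays and the variance, there were 447 in CA1 polysome RNA, 147 in CA3 polysome RNA, 0 for the region difference in polysome RNA in limma (554 at an unadjusted p under 0.05), 12 for the fraction difference in CA3 and 1253 for NIC CA1 against CA3. Array weights gave 2194 in CA1 polysome, 4748 in CA3 total and 744 in CA3 polysome RNA, 22 and 4 for the region differences in total and polysome RNA, 1544 and 2207 for the fraction differences in CA1 and CA3, and 1522 for NIC CA1 against CA3. At least 2-fold were 132 in CA1 total, 61 in CA1 polysome, 38 in CA3 total and 21 in CA3 polysome RNA, fewer by construction. The fraction differences in CA1 and CA3 were 2642 and 2179 with the pool as a replicate block, 3129 and 2824 with it as a fixed block, and 1614 and 721 with a block in the 8R pools only. The number as a replicate block gave 16 and 4 for the region differences in total and polysome RNA, and no block moved another count beyond 1.5 times. Without the 8R pool 4 arrays the counts were 4355 in CA3 total RNA, 15 and 1 for the region differences, 1081 and 1254 for the fraction differences and 1026 for NIC CA1 against CA3. Without each array in turn the counts ran from 2217 to 3403 in CA1 total, 423 to 1788 in CA1 polysome, 976 to 3013 in CA3 total and 89 to 366 in CA3 polysome RNA. They ran from 1 to 7 and 0 to 3 for the region differences in total and polysome RNA, 31 to 975 and 3 to 1023 for the fraction differences in CA1 and CA3, and 0 to 1 for the difference of these. The value of 0 is from limma, with 249 at an unadjusted p under 0.05 on all arrays, and the 1 was without 8R CA1 polysome replicate 2. For NIC they ran from 262 to 313 between regions and 6219 to 6520 between fractions. All 81 list tests called at the preset correlation were lost with an estimated one.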

Other observations

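The reading of the clock test was chosen after its result was seen, and the splits of whole pools were added after the other splits had been seen, as were the fits without pool 4 after the results on all arrays.

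In CA1 polysome RNA immediate early genes rose for 7 of 26 and fell for 3, 7 and 4 when adjusted over the list alone, with Arc at 1.33 and Atf3 at 1.31 among those that rose (camera adjusted p = 0.0435, and adjusted p = 0.719 with an estimated correlation). Astrocyte markers rose there for 3 of 14, and 3 when adjusted over the list alone (camera adjusted p = 0.0303, and adjusted p = 0.692 with an estimated correlation). Interneuron markers had a median of 0.20 with 0 of 13 called by limma (camera adjusted p = 0.0287, and adjusted p = 0.601 with an estimated correlation). The pool 4 array, 1 of 3, lay above the others by 0.29 for immediate early genes, 0.20 for astrocyte and 0.23 for interneuron markers, and without pool 4 none of these lists was called (camera adjusted p = 0.319, 0.268 and 0.131). In CA3 polysome RNA oxidative stress genes rose for 4 of 18, with 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0037, and adjusted p = 0.334 with an estimated correlation). CA1 pyramidal markers had a median of -0.17 in CA3 polysome RNA with 0 of 11 called by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.00543, and adjusted p = 0.627 with an estimated correlation).

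Respiratory chain genes differed between the control regions, lower in CA1 for 4 of 72, 5 when adjusted over the list alone (median -0.21, camera adjusted p = 1.45e-11, and adjusted p = 0.625 with an estimated correlation). Their polysome to total ratio after ischemia had a median of -0.29 in CA1, with 1 of 72 lower, and 8 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00313, and adjusted p = 0.778 with an estimated correlation). The pool 4 arrays were at -0.46 in CA1 polysome and -0.28 in CA1 total RNA for this list, in the direction of that change, and without pool 4 the median was -0.22. Cholesterol synthesis genes had medians of -0.26 and -0.30 for that ratio in CA1 and CA3 (camera adjusted p = 0.0439 and 0.0242, and adjusted p = 0.601 and 0.501 with an estimated correlation).

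The falls of Dbp and Nr1d1 raised the hypothesis of a different time of day at tissue collection. Medians of 8 evening-phase genes were -0.19 in CA1 and -0.02 in CA3 total RNA, and of 5 morning-phase genes 0.3 and 0.2, the signs that this explanation predicts, although -0.02 is near 0. Dbp and Nr1d1 are themselves evening-phase members, so these values are no independent test of the hypothesis they raised. The 2 evening-phase genes called lower in CA3 total RNA were Dbp and Nr1d1. In polysome RNA they were 0.02 and -0.01 for evening-phase and 0.02 in both regions for morning-phase genes, which in CA1 are not those signs. In total RNA 2 evening-phase genes were called lower in each region and 2 higher in CA1, and of the morning-phase genes 3 were called higher and 1 lower in CA1, and 1 higher in CA3. In polysome RNA 1 evening-phase gene was called lower in each region and 2 higher in CA1, and 2 morning-phase genes were called higher in CA1. Collection times are not given in the sources used here, so this explanation cannot be told apart from an effect of ischemia.

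Other splits of the same arrays were counted for each comparison. For CA1 total RNA 1 of 35 splits, the real one, gave as many as its 3346 genes, a share under 0.05, and the highest other gave 2046. The same held for CA3 polysome RNA (1 of 35, 338 genes, highest other 127) and for polysome against total RNA of controls (1 of 100, 6742 genes, highest other 4286). In these comparisons of 8R with NIC the highest other split set the NIC arrays and 1 8R array against the remaining 8R arrays. It therefore still carries the effect of ischemia. With 35 splits the share cannot fall below 0.0286, so chance is unlikely there but not excluded. For CA3 total RNA 2 of 35 splits gave as many as 1976. The highest other, with 2978, set the NIC arrays and the pool 4 array against the remaining 8R arrays, so it still carries the effect of ischemia and is no measure of chance, and the splits leave this count open. The rise of Hspb1 there (4.00 ± 0.31 SE) does not rest on the splits. The 24.6% of genes without overlap, against 5.71% by chance, comes from the same arrays and labels. Genes are not independent of each other, so that share is no separate support. For CA1 polysome RNA (1058 genes, highest other 0 in limma) and NIC CA1 against CA3 (441, highest other 0), 10 splits are too few for a share under 0.05, with 2934 and 1656 genes at an unadjusted p under 0.05 in the real splits. Between regions 8 of 100 splits in total RNA and 10 of 100 in polysome RNA gave as many as 3 and 2 genes (highest other 2901 and 1086). Between fractions 6 of 100 in CA1 and 10 of 100 in CA3 gave as many as 486 and 21 (2113 and 1956), and for the difference of these all 100 gave at least its 0 genes in limma (249 at an unadjusted p under 0.05, highest other 2717). In the highest splits for the region differences, and for the fraction difference in CA1, 8R and NIC were nearly exchanged within 1 group pair, so that they added the effects of ischemia instead of subtracting them, a structure of the samples. These splits are therefore no fair measure of chance for the differences between regions and fractions.

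Splits that moved all arrays of a pool number together place the effect of ischemia in the spread within groups, which lowers the counts of the other splits, so they do not measure chance either. The numbers were not borne out as pairs in NIC, so which NIC arrays moved together is arbitrary. Among them 1 of 35, the real one, gave as many as the 3 genes between regions in total RNA (highest other 0 in limma, with 664 at an unadjusted p under 0.05 in the real split) and the 21 between fractions in CA3 (highest other 2), and 1 of 35 as many as the 2179 with the pool as a replicate block (highest other 662). For the region difference in polysome RNA (2 genes, highest other 1), the fraction difference in CA1 (486, highest other 0 in limma, and 2642 with the pool as a replicate block, highest other 1671) and the difference of the fraction differences (0 in limma, as in all 20 splits), 20 splits are also too few for a share under 0.05. Whether chance accounts for the counts between regions and between fractions is therefore left open.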
